A study of Mus musculus with 18 samples.

How the data were processed

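RNA was sequenced from LSK cells of C57Bl/6 mice in 18 libraries. Of these, 6 came from freshly sorted cells, each pooled from 3 mice (3 control, 3 irradiated), and 12 from 200 LSK cells of 1 mouse cultured for 6 days and sorted again (3 each of control, irradiated, control with DL1 and irradiated with DL1). Irradiated mice had received 2.5 Gy and had recovered for at least 9 weeks. RNA was extracted with miRNeasy columns and libraries were made with TruSeq RNA reagents, as the labels state. The labels do not spell out DL1, which was read as Delta-like 1, and do not say how it was presented to the cells. They do not say whether cultures of the same number came from the same mouse.

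The authors deposited 2 tables of gene values in FPKM (fragments scaled by transcript length and library size), 1 for the freshly sorted and 1 for the cultured libraries. Their notes name TopHat 1.4.1, Cufflinks 1.3.0 and Cuffdiff, whose version is not given, and the human build hg19, although the samples are mouse. The build that was used, the annotation, the filters and any further scaling between libraries are not stated. Each table has 25629 rows with gene names in capitals. Names were matched to the current mouse symbols of a gene table for GRCm38.p6, used for names only: 19785 by symbol and 2916 by a synonym held by a single gene, while 2928 were left as listed, so that 88.58% were matched. Of the rows, 28 repeat a name of another row, 24 have names that look like dates and 123 hold several names joined by commas. Where rows shared a name, the row with the higher mean kept it. The tables were normalized separately, so no test was made across them.

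Columns were mapped to samples by title and table, and 0 columns were left unmapped. One column of the cultured table, whose name places the replicate number before DL1, was taken as irradiated replicate 1 with DL1, since the other 2 columns of that group carry the numbers 2 and 3 and irradiated replicate 1 without DL1 has a column of its own. The source field of the control samples names irradiated cells, whereas their titles and conditions say control. Titles and conditions were used.

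Relative depth was read from the values, since FPKM do not carry read counts. Within a library, the lowest values of genes under an FPKM of 1 are small whole multiples of a step that depends on depth and gene, and the ratio of these steps between libraries gives their relative depth. With up to 5 reads and a tolerance of 0.1%, between 27.7 and 33.6% of ratios fell on small fractions of the step, against 0.374 to 1.07% with a shifted step. The cultured libraries had depths between 0.756 and 1.09 of the first control, except irradiated replicate 2 with DL1 at 0.488, and the freshly sorted ones between 0.645 and 1 of theirs. FPKM summed to between 544392 and 576680 per cultured and between 762781 and 823321 per freshly sorted library. Rows that look like ribosomal or small RNA, a pattern of names chosen after the data had been seen, held between 32.3 and 35.0% of FPKM in freshly sorted libraries. The 18S row was 0 there except in control replicate 2, at 39327 FPKM.

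Genes with a mean FPKM of at least 1 over the libraries of a table were tested, 12903 in the freshly sorted and 12025 in the cultured table. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 4 cultured groups shared one fit. The comparisons were irradiated against control in freshly sorted cells, in cultures without DL1 and in cultures with DL1, DL1 against none in control and in irradiated cultures, and the difference between the changes after irradiation with and without DL1. Because the values are FPKM rather than counts, no count-based test was used.

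In each comparison 23 gene lists were considered, with 414 entries in all, 6 of which were not used here, and members below the expression filter were not tested. The lists, the comparisons, the tests, the rule for naming genes and most alternatives were written before the data were examined. Lists with at least 5 tested genes were tested with camera from limma at a preset correlation between genes of 0.01, and again with a correlation estimated per list and with fry, a rotation test that used statmod 1.5.0. Counts adjusted over the list alone use the p-values of the members of that list only. Genes were named where they were among the 10 that rose and the 10 that fell by the most without overlap of the groups (overlap was allowed for the difference between changes), where they had one of the 4 smallest p of a described list, or where they belonged to a fixed set of 6.

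Log2 fold changes of pairs of comparisons were correlated across genes without a p-value, since genes are not independent, and set beside other splits of the same libraries. Alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, median-ratio scaling, rescaling to a common total, fits without a trend, with robust variances, with library weights, with the replicate number as a block, with only the 2 groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. Rescaling without ribosomal RNA-like rows and a replicate block in 2 groups or in the irradiated cultures alone were added after the data had been seen, as were tests of the immediate early and heat shock list without Jun and Fos and of the myeloid differentiation list without macrophage markers. Libraries of the same number were checked for shared deviations from their group means. Only between irradiated cultures without and with DL1 did every number give a correlation over 0.1 (0.23, 0.14 and 0.35), and since the labels name no shared animal, batch or day, the values given are from fits without pairs and the block there is an alternative.

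The tests were tested on simulated data with 50 genes changed at each size of change. At 1.25-fold, 8% were recovered in the freshly sorted comparison, 64, 68, 64 and 72% in the comparisons of cultures in the order irradiation without DL1, irradiation with DL1, DL1 in control and DL1 in irradiated cells, and 26% for the difference between changes. At 1.5-fold these were 90, 94, 94, 100, 94 and 90%, and at 2-fold 98, 100, 100, 100, 98 and 96%. Unchanged genes made up between 2.16 and 6.31% of calls. The simulated changes had their full size on the log2(FPKM + 1) scale, with median log2 fold changes between 0.993 and 1.01 at 2-fold. At low FPKM, adding 1 holds a real change smaller, so recovery of such genes may be lower than these shares. Figures were made with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. No library was left out of the main analysis. Results for 4 single genes are not reported here.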

Results

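RNA sequencing was used to measure transcript levels in LSK cells of C57Bl/6 mice, the Lineage-negative, cKit-positive, Sca1-positive bone marrow cells that include hematopoietic stem cells and multipotent progenitors. The 18 libraries formed 6 groups of 3. Irradiated mice had received 2.5 Gy and had recovered for at least 9 weeks before their cells were taken. In 6 libraries, 3 control and 3 irradiated, LSK cells pooled from 3 mice were processed directly after sorting. In the other 12 libraries, 200 LSK cells of 1 mouse were grown for 6 days with stem cell factor, Flt3 ligand, interleukin-11 and interleukin-6 and were then sorted once more as LSK cells. The cultures made up 4 groups, control and irradiated, each without and with DL1, the usual abbreviation for the Notch ligand Delta-like 1. The title of the series sets the transcription factor C/EBPα, which drives myeloid differentiation, against Notch in the stem cell defects that follow irradiation.

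Levels are given as mean FPKM ± SD, and changes as log2 fold changes ± standard error on the log2(FPKM + 1) scale with adjusted p from limma, with n = 3 libraries per group unless stated. For a gene list the median log2 fold change of its tested genes is given with the adjusted p under a preset and under an estimated correlation between genes. Between 16879 and 18216 of the 25629 listed names had a value above 0 in a library. Relative sequencing depth was lowest in irradiated replicate 2 with DL1, at 0.488 of the first control culture. Cultured libraries of the same group correlated across genes with r between 0.988 and 0.997, and those of different groups with r between 0.941 and 0.995. Freshly sorted libraries correlated with r between 0.981 and 0.988 both within and between groups.

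In freshly sorted LSK cells, a small set of genes differed between mice irradiated at least 9 weeks earlier and controls. The AP-1 subunit gene Jun rose the most, from 3.41 ± 0.371 to 15.0 ± 3.27 FPKM (1.85 ± 0.15, adjusted p = 0.00359). It was followed by the tight junction scaffold gene Tjp1, from 3.85 ± 0.893 to 13.3 ± 0.833 (1.57 ± 0.14, adjusted p = 0.00741). Selp, which encodes the adhesion receptor P-selectin of platelets and endothelium, rose from 11.5 ± 2.28 to 31.0 ± 2.84 (1.36 ± 0.13, adjusted p = 0.00768). The thrombin receptor gene F2r rose from 26.0 ± 2.73 to 48.8 ± 4.07 (0.89 ± 0.099, adjusted p = 0.0205). Gfi1b, a transcriptional repressor needed for megakaryocyte and erythroid development, rose from 13.4 ± 1.52 to 24.3 ± 1.31 (0.81 ± 0.097, adjusted p = 0.0238). Cdkn2c, an inhibitor of the G1 cyclin-dependent kinases, rose from 11.99 ± 0.116 to 21.3 ± 0.327 (0.78 ± 0.073, adjusted p = 0.00741). The cytotoxic granule gene Nkg7 (0.78 ± 0.093, adjusted p = 0.0238), the myeloid hexokinase gene Hk3 (0.62 ± 0.082, adjusted p = 0.0477) and the predicted gene GM2397 (1.16 ± 0.089, adjusted p = 0.00359) rose as well.

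In freshly sorted irradiated cells Hif3a, a hypoxia-inducible factor subunit that can restrain its relatives, fell from 7.25 ± 0.958 to 1.77 ± 0.426 FPKM (-1.58 ± 0.15, adjusted p = 0.00741). Fkbp5, a co-chaperone of the glucocorticoid receptor, fell from 37.5 ± 4.02 to 20.2 ± 1.53 (-0.86 ± 0.10, adjusted p = 0.0238). Serpinf1, which encodes a secreted anti-angiogenic factor, fell from 31.0 ± 1.85 to 14.1 ± 0.380 (-1.08 ± 0.078, adjusted p = 0.00359). The transporter gene Abcg3 fell from 6.39 ± 0.965 to 2.65 ± 0.159 (-1.01 ± 0.12, adjusted p = 0.0294). In all, 13 of 12903 genes passed, 9 higher and 4 lower, 7 of them with an absolute log2 fold change of at least 1. Without adjustment 886 genes had p under 0.05, and the groups did not overlap for 12.7% of genes, where chance gives 10%.

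**Figure D1:**
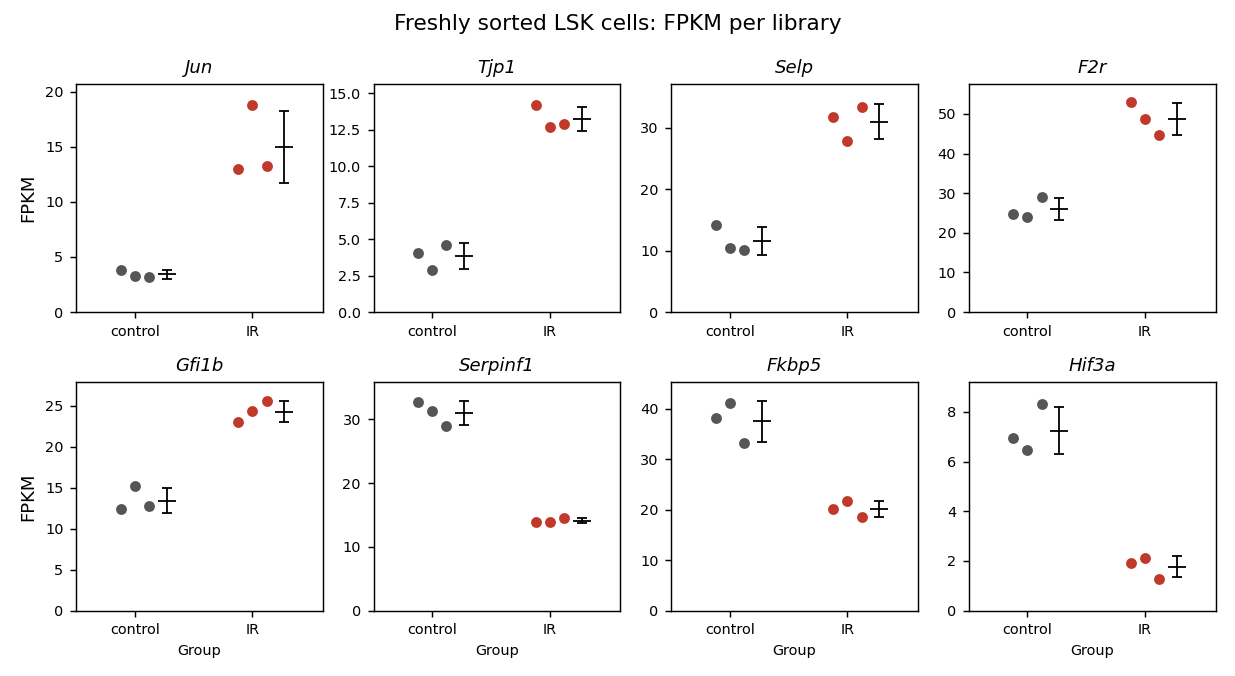
Levels of 8 genes in freshly sorted LSK cells of control and irradiated mice. Points are libraries, with the mean ± SD beside them.

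Of the fixed gene lists, 4 of 23 passed in freshly sorted cells under a preset correlation, all upward. The megakaryocyte list had the largest shift, with 11 of its 12 tested genes higher (median 0.47, adjusted p = 3.96e-07, adjusted p = 0.765 with an estimated correlation). Selp alone rose over all genes, and 7 genes rose and 1 fell adjusted over the list alone. Gp5, a subunit of the platelet von Willebrand factor receptor (0.72 ± 0.12), and the integrin gene Itga2b (0.44 ± 0.12) were higher without passing. In the cell cycle list 24 of 28 genes were higher by small amounts (median 0.12, adjusted p = 0.00341, adjusted p = 0.823 with an estimated correlation). None passed over all genes in limma or over the list alone, and Ccnb1 (0.35 ± 0.10), Mki67 (0.27 ± 0.080), Aurkb (0.24 ± 0.096) and Tk1 (0.22 ± 0.092) had the smallest p. The immediate early and heat shock list held Jun and Fos, its AP-1 partner, which did not pass (1.51 ± 0.21, adjusted p = 0.0523). In a test chosen after the values were seen, the list did not pass without these 2 genes, with 9 of 12 higher (adjusted p = 0.419). Junb was higher (0.35 ± 0.14) and the heat shock gene Hsph1 lower (-0.58 ± 0.16) without passing. Of its 14 tested genes 1 rose, against 2 that rose and 1 that fell over the list alone (median 0.25, adjusted p = 0.0106, adjusted p = 0.823 with an estimated correlation). The myeloid differentiation list was higher for 17 of 20 genes, none of which passed in either way (median 0.22, adjusted p = 0.0370, adjusted p = 0.823 with an estimated correlation). The granule protease genes Ctsg, Prtn3 and Elane and the membrane gene Ms4a3 had the smallest p, at 0.62 ± 0.24, 0.28 ± 0.11, 0.51 ± 0.23 and 0.60 ± 0.27. Its call was lost with a pseudocount of 0.1 (adjusted p = 0.0587), without the filter on the mean (adjusted p = 0.0797) and without control replicates 1 and 3 and irradiated replicate 2 (adjusted p = 0.505, 0.256 and 0.384). The cell cycle list was lost without control replicate 3 and irradiated replicate 1 (adjusted p = 0.0921 and 0.0636) and the immediate early and heat shock list without control replicate 1 and irradiated replicate 2 (adjusted p = 0.0644 and 0.369), so that 2 lists passed without irradiated replicate 2. The megakaryocyte list passed without each library in turn. Of the 10 splits of these libraries into groups of 3, the real one included, 9 gave at least 4 lists.

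Neither the p53 and DNA damage response list (adjusted p = 0.518) nor the interferon response list (adjusted p = 0.112) passed in freshly sorted cells, and none of their genes did in limma. Cebpa stood at 8.86 ± 3.64 FPKM in control and 8.27 ± 0.696 in irradiated cells and did not pass (-0.027 ± 0.23, adjusted p = 0.994). The receptor gene Notch1 was lower in every irradiated library, 7.53 ± 0.267 against 10.1 ± 0.626, but did not pass (-0.37 ± 0.088, adjusted p = 0.319). The p53 target gene Cdkn1a (0.14 ± 0.15) and the genes of the sort markers, Kit (0.073 ± 0.096) and Ly6a (-0.16 ± 0.21), did not pass either, and the Notch target gene Hes1 lay below the expression filter. Calls in this comparison hung on single libraries. Without irradiated replicate 1 only 5 genes passed, and Tjp1 (adjusted p = 0.0522), Selp (adjusted p = 0.0610), Cdkn2c (adjusted p = 0.0607) and Hif3a (adjusted p = 0.0517) were lost. F2r, Gfi1b, Nkg7, Hk3, Abcg3 and Fkbp5 were each lost without at least 4 of the 6 libraries in turn (adjusted p between 0.0517 and 0.210). Without ribosomal RNA-like rows 12 genes were higher and 11 lower. Without the filter on the mean 4 genes passed. Only Serpinf1 and GM2397 passed under every alternative in which single genes were followed, so Jun too was lost under some alternative.

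Far more genes passed between irradiated and control LSK cells in cultures without DL1 (3568) than in freshly sorted cells (13). The fits differed in power, with 12 cultured against 6 freshly sorted libraries. The smallest simulated change was recovered for 64% of genes in culture and 8% in freshly sorted cells. With only the 2 groups compared, 1657 genes passed in culture. The counts therefore do not tell whether the changes were larger in culture. In irradiated cultures Cebpa rose from 51.7 ± 3.15 to 76.6 ± 3.36 FPKM (0.56 ± 0.083, adjusted p = 9.06e-04). Cebpe, its relative needed for granule formation in granulocytes, rose from 13.1 ± 0.158 to 32.2 ± 5.45 (1.22 ± 0.14, adjusted p = 2.85e-04). The C/EBP family list did not pass with camera, with 2 genes rising and 1 falling of 6 (adjusted p = 0.208). With fry, an alternative list test, it passed upward (adjusted p = 0.00671). The granule protease gene Elane rose from 509.7 ± 33.6 to 1234 ± 218 (1.26 ± 0.14, adjusted p = 2.20e-04). Flt3, a receptor of lymphoid-primed progenitors, fell from 14.5 ± 1.67 to 6.23 ± 1.29 (-1.11 ± 0.13, adjusted p = 2.85e-04). The proliferation marker gene Mki67 fell from 79.3 ± 7.13 to 55.1 ± 4.09 (-0.52 ± 0.071, adjusted p = 6.24e-04).

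Among the genes that rose most in irradiated cultures, the lipoprotein gene Apoe rose from 191 ± 47.9 to 618 ± 146 FPKM (1.69 ± 0.18, adjusted p = 1.57e-04). The complement genes C1qb, from 23.0 ± 8.18 to 86.6 ± 19.0 (1.90 ± 0.23, adjusted p = 3.22e-04), and C1qc (1.94 ± 0.24, adjusted p = 3.31e-04) rose with it. The scavenger receptor-like gene Fcrls rose from 3.22 ± 1.4 to 16.1 ± 4.88 (2.03 ± 0.23, adjusted p = 2.33e-04). The mannose receptor gene Mrc1 rose from 6.28 ± 2.36 to 25.1 ± 10.03 (1.81 ± 0.28, adjusted p = 0.00103). Chil3, a chitinase-like lectin listed as CHI3L3 (1.80 ± 0.26, adjusted p = 8.00e-04), and the arginase gene Arg1 (1.65 ± 0.28, adjusted p = 0.00196) rose in the same samples. The myosin light chain gene Myl10 rose from 7.77 ± 1.17 to 33.5 ± 3.39 (1.98 ± 0.13, adjusted p = 8.96e-06) and the uncharacterised LOC100504670 rose too (2.62 ± 0.58, adjusted p = 0.00675). The small nucleolar RNA Snord111, listed at 0 in every control, rose to 3.30 ± 1.22 (adjusted p = 0.0195; 0.0515, 0.0576 and 0.0716 without control replicates 1 and 2 and irradiated replicate 1).

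Among the genes that fell most in irradiated cultures, Egfl7, a secreted factor of endothelial and stem cells, fell from 62.1 ± 3.50 to 34.0 ± 8.81 FPKM (-0.88 ± 0.14, adjusted p = 0.00132). The pseudokinase gene Ptk7 fell from 9.91 ± 0.389 to 4.48 ± 0.261 (-0.99 ± 0.073, adjusted p = 1.83e-05), and the channel gene Aqp9 from 16.5 ± 0.608 to 8.52 ± 0.498 (-0.88 ± 0.049, adjusted p = 3.05e-06). The lymphocyte GTPase gene Gimap6 (-0.90 ± 0.15, adjusted p = 0.00154), the GTPase gene Gem (-1.04 ± 0.23, adjusted p = 0.00621) and Rps4l, a ribosomal protein gene listed as RPS4Y2 (-0.88 ± 0.19, adjusted p = 0.00591), fell too. The globin gene Hbb-b1 fell (-1.14 ± 0.38, adjusted p = 0.0392), a call lost without any 1 of 5 libraries, with adjusted p = 0.162 without irradiated replicate 1. The uncharacterised LOC100503083 (-1.09 ± 0.14, adjusted p = 4.70e-04) and LOC100503605 (-1.07 ± 0.35, adjusted p = 0.0378) fell. The latter was lost without any 1 of 5 libraries (adjusted p = 0.156 without irradiated replicate 1).

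Of 19 lists tested in irradiated cultures 8 passed, with more myeloid and fewer cell cycle transcripts. Elane, Flt3 and Mki67 are themselves members of these lists. Of the 10 splits of these libraries, the real one included, 4 gave at least 8 lists. Irradiated replicate 3 correlated better with the controls (r between 0.990 and 0.992) than with irradiated replicate 1 (0.988), and with irradiated replicate 2 at 0.993. Of 21 myeloid differentiation genes 17 rose and 0 fell, 19 adjusted over the list alone (median 0.61, adjusted p = 5.85e-11, adjusted p = 0.322 with an estimated correlation). Beside Elane they included Gfi1 (0.96 ± 0.10), Mpo (0.88 ± 0.10) and Prtn3 (0.52 ± 0.070). Macrophage markers, chosen after values were seen, moved with them, 23 of 24 rising, and without the 5 of them in this list 13 of its 16 other genes rose (adjusted p = 1.92e-09, adjusted p = 0.322 with an estimated correlation). Of 28 cell cycle genes 25 fell and 0 rose, 27 over the list alone (median -0.29, adjusted p = 1.21e-10, adjusted p = 0.322 with an estimated correlation). Beside Mki67 these included Ccne1 (-0.55 ± 0.071), Top2a (-0.44 ± 0.062) and Bub1b (-0.48 ± 0.067). The mature neutrophil list had 5 genes that rose of 9, against 5 that rose and 1 that fell over the list alone (median 0.59, adjusted p = 0.00276, adjusted p = 0.322 with an estimated correlation). The clearest were S100a8 (1.41 ± 0.18), S100a9 (1.45 ± 0.20), Lcn2 (0.36 ± 0.055) and Ngp (1.28 ± 0.21). In the mast cell, basophil and eosinophil list 7 of 14 rose, 8 over the list alone (median 0.53, adjusted p = 4.00e-05, adjusted p = 0.322 with an estimated correlation). These included Cd63 (1.3 ± 0.073), Hdc (0.90 ± 0.079), Mcpt8 (0.76 ± 0.13) and Prg2 (1.60 ± 0.35), Cd63 being a tetraspanin gene of granules. In the megakaryocyte list 3 of 7 rose, also over the list alone (median 0.21, adjusted p = 0.0156, adjusted p = 0.322 with an estimated correlation). These were Pf4 (1.35 ± 0.14), Ppbp (1.56 ± 0.20) and Itga2b (0.63 ± 0.099), the first 2 being platelet chemokine genes. In lymphoid priming and B lineage 5 of 8 genes fell and 1 rose, also over the list alone (median -0.31, adjusted p = 0.0268, adjusted p = 0.322 with an estimated correlation). After Flt3, Mef2c (-0.52 ± 0.056), Cd79b (-0.43 ± 0.093) and Satb1 (-0.38 ± 0.086) fell most clearly, but the list did not pass without irradiated replicate 3 (adjusted p = 0.0789) or without the filter on the mean (adjusted p = 0.428).

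Interferon response genes were modestly higher in irradiated cultures, 5 of 18 rising, also over the list alone (median 0.15, adjusted p = 0.0265, adjusted p = 0.551 with an estimated correlation and 0.134 with fry). The smallest p belonged to Ifit2 (0.39 ± 0.074), Igtp (0.35 ± 0.078), Cxcl10 (0.65 ± 0.17) and Irf7 (0.45 ± 0.12). The calls of the list (adjusted p = 0.312), Cxcl10 (adjusted p = 0.0559) and Irf7 (adjusted p = 0.0795) were lost without irradiated replicate 1, those of the list (adjusted p = 0.0890) and Irf7 (adjusted p = 0.0860) without control replicate 2, and that of Irf7 without control replicate 1 (adjusted p = 0.05005). Oxidative phosphorylation genes were slightly lower, 6 of 23 falling and 1 rising, also over the list alone (median -0.085, adjusted p = 0.0476, adjusted p = 0.742 with an estimated correlation and 0.1385 with fry). Cycs (-0.33 ± 0.064), Sdhb (-0.19 ± 0.054) and Atp5o (-0.23 ± 0.066) fell and Ndufa1 rose (0.24 ± 0.072). The calls of the list (adjusted p between 0.0647 and 0.246), Atp5o (between 0.0611 and 0.0908) and Sdhb (between 0.0576 and 0.0781) were lost without control replicates 2 and 3 and irradiated replicates 1 and 2 in turn, and that of Ndufa1 without control replicate 1 and irradiated replicate 2 (adjusted p = 0.0677 and 0.0680). The list was also lost with median-ratio scaling (adjusted p = 0.0808) and with a pseudocount of 0.1 (adjusted p = 0.0512). The p53 and DNA damage response list did not pass (adjusted p = 0.0666), with 6 genes that rose and 1 that fell of 21. Neither did the Notch target genes (adjusted p = 0.118), where 2 of 6 fell, the cyclin gene Ccnd1 among them (-0.78 ± 0.075, adjusted p = 1.03e-04). With fry both lists passed, the p53 list upward (adjusted p = 0.0305) and the Notch target list downward (adjusted p = 0.00914). Notch1 (0.24 ± 0.091, adjusted p = 0.0608), Hes1 (-0.11 ± 0.12), Cdkn1a (0.15 ± 0.12), Kit (0.024 ± 0.073) and Ly6a (0.15 ± 0.094) did not pass.

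In total 3568 of 12025 genes passed between irradiated and control cultures, 1660 higher and 1908 lower, 84 of them, 78 higher and 6 lower, with an absolute log2 fold change of at least 1. Unadjusted p was under 0.05 for 5007 genes, and 38.1% of genes had groups without overlap, where chance gives 10%. The split of direction depended on scaling, with 2021 higher and 1473 lower after median-ratio scaling. The count was 1876 without control replicate 2 and 2180 without irradiated replicate 1. Ribosomal RNA-like and small RNA rows took 3.72, 2.85 and 1.58% of FPKM in the irradiated cultures and 1.70, 2.05 and 1.69% in the controls.

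With DL1 in control cultures Hes1, a direct target of Notch, rose from 0.637 ± 0.151 to 2.95 ± 0.366 FPKM (1.27 ± 0.12, adjusted p = 1.46e-05). Tcf7, which starts the T lineage program downstream of Notch, rose from 4.43 ± 1.18 to 38.9 ± 10.8 (2.87 ± 0.25, adjusted p = 7.61e-06). The T and natural killer cell surface gene Cd7 rose from 3.77 ± 0.979 to 35.5 ± 5.22 (2.95 ± 0.27, adjusted p = 1.11e-05). The granzyme genes Gzmb, from 1.02 ± 0.103 to 17.6 ± 1.80 (3.20 ± 0.076, adjusted p = 2.01e-10), and Gzmc, from 0.631 ± 0.0850 to 30.5 ± 5.19 (4.26 ± 0.14, adjusted p = 5.11e-09), rose with it. Apoe fell from 191 ± 47.9 to 21.4 ± 2.08 (-3.08 ± 0.18, adjusted p = 6.95e-07) and the matrix gene Fn1 from 19.7 ± 1.78 to 0.656 ± 0.243 (-3.65 ± 0.17, adjusted p = 2.79e-07). Cebpa fell slightly, from 51.7 ± 3.15 to 43.1 ± 1.79 (-0.26 ± 0.083, adjusted p = 0.0396).

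Among further genes with large changes under DL1 in control cultures, the mast cell protease genes Mcpt1 (5.61 ± 0.67, adjusted p = 7.14e-05), Mcpt2 (3.51 ± 0.67, adjusted p = 0.00201) and Mcpt4 (3.01 ± 0.62, adjusted p = 0.00352) rose, while the mast cell, basophil and eosinophil list did not pass, with 4 of 14 genes rising (adjusted p = 0.120). The spread of Mcpt1 was wide, at 90.1 ± 83.0 FPKM with DL1. Itgax, the CD11c integrin gene of dendritic cells (2.84 ± 0.22, adjusted p = 3.32e-06), and the uncharacterised LOC100504495 (2.65 ± 0.31, adjusted p = 6.58e-05) rose. Genes that fell included the glycoprotein gene Gpnmb (-3.37 ± 0.20, adjusted p = 6.95e-07), the acute phase gene Saa3 (-3.34 ± 0.23, adjusted p = 1.57e-06) and the lipid receptor gene Trem2 (-3.26 ± 0.19, adjusted p = 5.93e-07). The scavenger receptor genes Msr1 (-2.75 ± 0.21, adjusted p = 3.03e-06) and Stab1 (-2.68 ± 0.18, adjusted p = 1.20e-06) fell as well. The complement receptor gene C5ar1 (-2.57 ± 0.15, adjusted p = 6.95e-07), the clotting factor gene F13a1 (-2.54 ± 0.16, adjusted p = 9.37e-07) and Chil3 (-2.51 ± 0.26, adjusted p = 2.64e-05) fell in the same samples.

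With DL1 in control cultures 8 of 19 lists passed. Of 6 Notch target genes 5 rose and 0 fell, also over the list alone (median 0.92, adjusted p = 8.96e-04, adjusted p = 0.189 with an estimated correlation). Beside Tcf7 and Hes1, Gata3 (1.28 ± 0.16) and Ccnd1 (0.38 ± 0.075) rose. Of 6 early T lineage genes 5 rose, also over the list alone (median 1.12, adjusted p = 0.00887, adjusted p = 0.189 with an estimated correlation). Gata3, Tcf7 and Cd7 were among them, and the exception was Thy1, which fell (-1.67 ± 0.14, adjusted p = 6.60e-06). Of 21 myeloid differentiation genes 16 fell and 0 rose, against 18 and 1 over the list alone (median -0.62, adjusted p = 1.26e-11, adjusted p = 0.189 with an estimated correlation). The smallest p were those of Lyz2 (-2.27 ± 0.18), Mgst1 (-0.88 ± 0.087), Ly6c2 (-1.41 ± 0.15) and Cd14 (-1.27 ± 0.14), of which Lyz2 and Cd14 are also macrophage markers. Of 24 such markers 21 fell, and without the 5 of them in this list 13 of its 16 other genes fell (adjusted p = 9.16e-09, adjusted p = 0.189 with an estimated correlation). In the mature neutrophil list 5 of 9 fell, 6 over the list alone, and the chemokine receptor gene Cxcr2 rose in both (median -1.01, adjusted p = 2.30e-04, adjusted p = 0.233 with an estimated correlation). Here Lcn2 (-1.01 ± 0.055), Ltf (-2.13 ± 0.18), Mmp8 (-1.53 ± 0.14) and Ngp (-2.2 ± 0.21) fell most clearly. Interferon response genes rose for 11 of 18 and fell for 1, also over the list alone (median 0.42, adjusted p = 7.98e-05, adjusted p = 0.345 with an estimated correlation). Clearest were Bst2 (0.62 ± 0.051), Irgm1 (0.34 ± 0.045), Usp18 (1.27 ± 0.17) and Isg15 (1.16 ± 0.18). Antigen presentation and dendritic cell genes rose for 5 of 12, 6 over the list alone (median 0.48, adjusted p = 0.00233, adjusted p = 0.562 with an estimated correlation). Itgax was followed by Batf3 (1.47 ± 0.20), Irf4 (0.67 ± 0.13) and Ccr7 (0.92 ± 0.22). Smaller upward shifts passed for oxidative phosphorylation, where 8 of 23 rose, 9 over the list alone (median 0.13, adjusted p = 0.0219, adjusted p = 0.616 with an estimated correlation). These included Cox5a (0.32 ± 0.054), Ndufa1 (0.35 ± 0.072), Cox7b (0.23 ± 0.060) and Ndufa4 (0.25 ± 0.072). The cell cycle list passed with 4 of 28 genes rising, 2 over the list alone (median 0.11, adjusted p = 0.0319, adjusted p = 0.616 with an estimated correlation), namely Ccne1 (0.27 ± 0.071), Aurkb (0.24 ± 0.065), Tk1 (0.18 ± 0.057) and Bub1b (0.21 ± 0.067). The oxidative phosphorylation list was lost without control replicate 1 (adjusted p = 0.0956) and the cell cycle list without control replicate 3 and DL1 replicate 3 (adjusted p = 0.105 and 0.0604).

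Notch1 itself fell with DL1 in control cultures, from 13.0 ± 0.704 to 9.14 ± 0.174 FPKM (-0.46 ± 0.091, adjusted p = 0.00262), whereas Flt3 rose from 14.5 ± 1.67 to 29.1 ± 3.60 (0.96 ± 0.13, adjusted p = 1.95e-04). Ly6a (0.27 ± 0.094, adjusted p = 0.0503), Kit (0.16 ± 0.073) and Cdkn1a (0.10 ± 0.12) did not pass. In all 3154 of 12025 genes passed, 1675 higher and 1479 lower, 359 of them, 137 higher and 222 lower, with an absolute log2 fold change of at least 1. Unadjusted p was under 0.05 for 4526, and 48.3% had groups without overlap, where chance gives 10%. Median-ratio scaling turned the split to 1260 higher and 1714 lower. The call of Cebpa was lost without control replicates 1 and 2 (adjusted p = 0.0764 and 0.135) and without DL1 replicates 1, 2 and 3 (adjusted p = 0.0793, 0.0672 and 0.132). So were those of Cox7b, Ndufa4, Ccne1, Aurkb, Tk1 and Bub1b without control replicate 1 (adjusted p between 0.0525 for Aurkb and 0.130 for Tk1) and without DL1 replicate 1 (between 0.0520 for Cox7b and 0.0892 for Ndufa4). Ndufa4, Aurkb, Tk1 and Bub1b were lost without DL1 replicate 3 too (adjusted p between 0.0540 and 0.157), Tk1 without DL1 replicate 2 (adjusted p = 0.0994), and Bub1b without each of the 6 libraries.

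DL1 acted on irradiated cultures in much the same way. Hes1 rose from 0.522 ± 0.152 to 2.06 ± 0.449 FPKM (1.004 ± 0.12, adjusted p = 5.27e-05) and Tcf7 from 3.85 ± 1.29 to 32.9 ± 10.1 (2.80 ± 0.25, adjusted p = 5.22e-06). Flt3, which irradiation had lowered, rose from 6.23 ± 1.29 to 23.3 ± 2.26 (1.76 ± 0.13, adjusted p = 1.58e-06). Mki67 rose from 55.1 ± 4.09 to 91.8 ± 2.69 (0.73 ± 0.071, adjusted p = 9.54e-06). Cebpa fell from 76.6 ± 3.36 to 57.9 ± 7.93 (-0.41 ± 0.083, adjusted p = 0.00229), and Apoe from 618 ± 146 to 40.1 ± 3.54 (-3.89 ± 0.18, adjusted p = 1.04e-07).

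Among the genes with the largest changes under DL1 in irradiated cultures, Mcpt1 (4.998 ± 0.67, adjusted p = 1.14e-04), Mcpt2 (3.06 ± 0.67, adjusted p = 0.00334) and Gzmc (4.32 ± 0.14, adjusted p = 4.30e-09) rose. The mast cell, basophil and eosinophil list did not pass, with 3 of 14 genes rising and 5 falling (adjusted p = 0.229). So did Cd7 (3.20 ± 0.27, adjusted p = 3.50e-06) and Itgax (3.24 ± 0.22, adjusted p = 8.08e-07). With them rose the ubiquitin ligase gene Asb2, a known target of Notch (3.07 ± 0.18, adjusted p = 3.08e-07), the apolipoprotein L gene Apol7c (2.96 ± 0.29, adjusted p = 9.59e-06) and the cadherin gene Cdh1 (2.93 ± 0.34, adjusted p = 3.94e-05). Fn1 (-4.00 ± 0.17, adjusted p = 7.27e-08), Mrc1 (-3.86 ± 0.28, adjusted p = 1.21e-06) and Gpnmb (-3.59 ± 0.20, adjusted p = 2.32e-07) fell, as did Trem2 (-3.53 ± 0.19, adjusted p = 1.89e-07) and C5ar1 (-3.38 ± 0.15, adjusted p = 9.82e-08). Stab1 (-3.37 ± 0.18, adjusted p = 1.89e-07), Fcrls (-3.35 ± 0.23, adjusted p = 9.71e-07), Saa3 (-3.14 ± 0.23, adjusted p = 1.30e-06) and the membrane protein gene Tmem37 (-3.18 ± 0.17, adjusted p = 2.00e-07) fell as strongly.

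In irradiated cultures DL1 shifted 9 of 19 lists. The cell cycle list was the broadest, with 27 of 28 genes rising and all 28 over the list alone (median 0.32, adjusted p = 1.24e-07, adjusted p = 0.351 with an estimated correlation). Beside Mki67, Ccne1 (0.71 ± 0.071), Bub1b (0.60 ± 0.067) and Top2a (0.47 ± 0.062) rose. Of 21 myeloid differentiation genes 18 fell, 19 over the list alone, and Spi1 alone rose in both (median -0.69, adjusted p = 5.98e-10, adjusted p = 0.204 with an estimated correlation). The smallest p were those of Lyz2 (-2.28 ± 0.18), Fcgr3 (-1.28 ± 0.13), Cd14 (-1.38 ± 0.14) and Mgst1 (-0.83 ± 0.087). Lyz2 and Cd14 are also macrophage markers, all 24 of which fell. Without the 5 of them in this list, 13 of its 16 other genes fell and 1 rose (adjusted p = 2.15e-07, adjusted p = 0.220 with an estimated correlation). In the mature neutrophil list 7 of 9 fell and 1 rose, also over the list alone (median -0.78, adjusted p = 0.00112, adjusted p = 0.320 with an estimated correlation). Cxcr2 rose (0.75 ± 0.088), while Lcn2 (-0.78 ± 0.055), Ltf (-2.11 ± 0.18) and Ngp (-1.70 ± 0.21) fell. Notch target genes rose for 5 of 6, also over the list alone (median 0.97, adjusted p = 0.00279, adjusted p = 0.204 with an estimated correlation), Ccnd1 (0.94 ± 0.075) and Gata3 (1.13 ± 0.16) among them. Early T lineage genes, 5 of 6 of which rose, did not pass as a list with camera (adjusted p = 0.0619). With fry the list passed upward (adjusted p = 3.17e-04). Interferon response genes rose for 13 of 18, 14 over the list alone (median 0.34, adjusted p = 0.00112, adjusted p = 0.351 with an estimated correlation). Clearest were Bst2 (0.55 ± 0.051), Ifi27l2a (1.62 ± 0.18), Usp18 (1.4 ± 0.17) and Irgm1 (0.29 ± 0.045). Antigen presentation and dendritic cell genes rose for 5 of 12, 6 over the list alone (median 0.55, adjusted p = 0.00705, adjusted p = 0.501 with an estimated correlation; 0.0746 without irradiated replicate 3). After Itgax came Batf3 (1.47 ± 0.20), Irf4 (0.91 ± 0.13) and Ccr7 (1.42 ± 0.22). Oxidative phosphorylation genes rose for 12 of 23, 13 over the list alone (median 0.15, adjusted p = 0.00705, adjusted p = 0.501 with an estimated correlation), with Cox5a (0.39 ± 0.054), Sdhb (0.30 ± 0.054) and Cox7b (0.32 ± 0.060).

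Genes for Notch receptors, ligands and processing moved down with DL1 in irradiated cultures, 7 of 15 falling and 1 rising, also over the list alone (median -0.15, adjusted p = 0.0140, adjusted p = 0.351 with an estimated correlation). The secretase gene Psen2 (-0.72 ± 0.075, adjusted p = 1.50e-05) and the sheddase genes Adam10 (-0.42 ± 0.054) and Adam17 (-0.36 ± 0.057) fell, as did Notch1, from 15.7 ± 2.67 to 10.04 ± 0.268 FPKM (-0.58 ± 0.091, adjusted p = 3.49e-04). The megakaryocyte list, 4 of 7 genes falling and 1 rising, did not pass (adjusted p = 0.0617, adjusted p = 0.320 with an estimated correlation). It did under a preset correlation with a replicate block in these 2 groups (adjusted p = 0.00934) and, without a block, downward with fry (adjusted p = 9.39e-04). In the stem cell self-renewal list 7 of 18 genes fell and 3 rose, also over the list alone (median -0.092, adjusted p = 0.0338, adjusted p = 0.204 with an estimated correlation). The genes Hlf (-0.85 ± 0.094), Hoxa9 (-1.31 ± 0.17) and Erg (-0.39 ± 0.066) fell, and the list was lost without irradiated replicate 3 or irradiated replicate 1 with DL1 (adjusted p = 0.0746 or 0.0502). Kit (-0.048 ± 0.073), Ly6a (0.11 ± 0.094) and Cdkn1a (-0.20 ± 0.12) did not pass. In total 4974 of 12025 genes passed, 2931 higher and 2043 lower, 441 of them, 151 higher and 290 lower, with an absolute log2 fold change of at least 1. Unadjusted p was under 0.05 for 6097, and 48.3% of genes had groups without overlap. After median-ratio scaling 2019 were higher and 2475 lower. That more genes passed than in control cultures depended on the fit, with 3564 against 3693 when only the 2 groups compared were fitted and 4554 against 4688 with library weights.

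**Figure D2:**
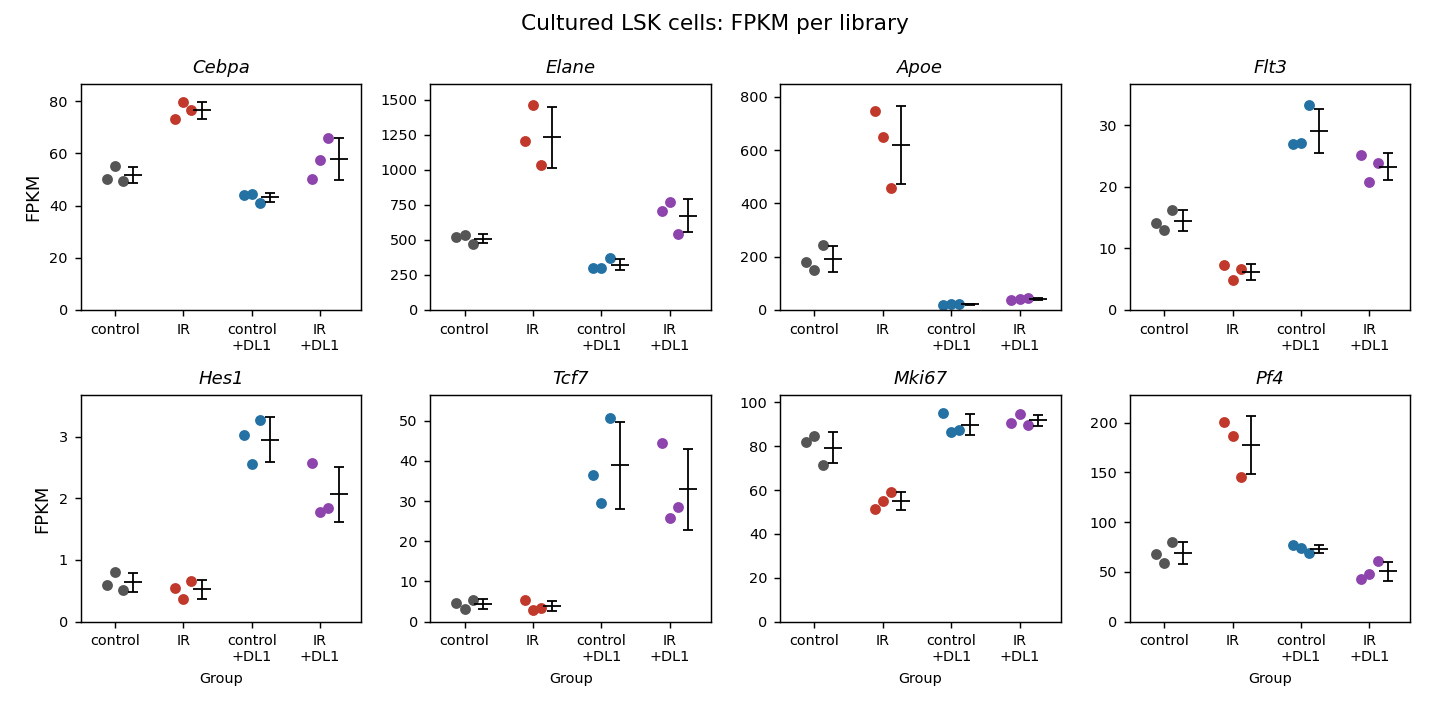
Levels of 8 genes in cultured LSK cells of control and irradiated mice, without and with DL1. Points are libraries, with the mean ± SD beside them.

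Between control and irradiated cultures with DL1, Ngp, a granule protein gene of neutrophils, rose from 8.45 ± 1.2 to 32.0 ± 7.76 FPKM (1.78 ± 0.21, adjusted p = 0.00245). The alarmin genes S100a8, from 319 ± 34.3 to 716 ± 156 (1.14 ± 0.18, adjusted p = 0.00761), and S100a9, from 244 ± 29.9 to 554 ± 103 (1.17 ± 0.20, adjusted p = 0.00954), rose with it. Elane rose from 323 ± 40.0 to 673 ± 117 (1.05 ± 0.14, adjusted p = 0.00450). Cebpa rose from 43.1 ± 1.79 to 57.9 ± 7.93 (0.41 ± 0.083, adjusted p = 0.0228) and Cebpe from 14.8 ± 1.45 to 26.5 ± 5.63 (0.78 ± 0.14, adjusted p = 0.0146).

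Other genes that rose most in irradiated cultures with DL1 were the matrix glycoprotein gene Thbs1 (1.253 ± 0.15, adjusted p = 0.00312), the monocyte surface gene Ly6c2 (1.09 ± 0.15, adjusted p = 0.00450) and Gpnmb (1.19 ± 0.20, adjusted p = 0.00898). Saa3 (1.15 ± 0.23, adjusted p = 0.0210), C1qc (1.16 ± 0.24, adjusted p = 0.0229), Chil3 (1.2 ± 0.26, adjusted p = 0.0314) and the ficolin gene Fcnb (1.19 ± 0.28, adjusted p = 0.0386) rose with them. Those that fell most included Gimap6 (-0.89 ± 0.15, adjusted p = 0.00822), the proto-oncogene Mycn (-0.85 ± 0.17, adjusted p = 0.0214) and the bone morphogenetic protein receptor gene Bmpr1a (-0.69 ± 0.088, adjusted p = 0.00392). The imprinted noncoding RNA Rian (-0.65 ± 0.15, adjusted p = 0.0372) fell with its neighbour in the combined row MEG3,MIR770 (-0.63 ± 0.13, adjusted p = 0.0291). The peptidoglycan recognition gene Pglyrp2 (-0.77 ± 0.15, adjusted p = 0.0210) and the scramblase gene Plscr2 (-0.70 ± 0.14, adjusted p = 0.0177) fell too. So did the uncharacterised LOC100503730 (-0.98 ± 0.20, adjusted p = 0.0229), LOC100503083 (-0.90 ± 0.14, adjusted p = 0.00761) and LOC100503365 (-0.78 ± 0.17, adjusted p = 0.0342). Of these, Saa3, C1qc, Chil3, Fcnb, Mycn, Rian, MEG3,MIR770, Pglyrp2, Plscr2, LOC100503730 and LOC100503365 were each lost without at least 3 of the 6 libraries compared in turn, Fcnb reaching an adjusted p of 0.169 without irradiated replicate 2. S100a9 was lost without that library (adjusted p = 0.0577).

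With DL1, 9 of 19 lists passed between irradiated and control cultures. Of 21 myeloid differentiation genes 13 rose and 0 fell, 19 over the list alone (median 0.53, adjusted p = 5.90e-20, adjusted p = 0.0872 with an estimated correlation). Beside Elane and Ly6c2, Mgst1 (0.63 ± 0.087) and Gfi1 (0.73 ± 0.10) rose. Of 24 macrophage markers 7 rose as well. Without the 5 markers in this list, 12 of its 16 other genes rose (adjusted p = 2.42e-18, adjusted p = 0.0636 with an estimated correlation). In the mature neutrophil list 4 of 9 rose, 7 over the list alone (median 0.58, adjusted p = 7.81e-08, adjusted p = 0.0872 with an estimated correlation). The siderophore-binding gene Lcn2 had the smallest p (0.58 ± 0.055, adjusted p = 8.82e-04). In the C/EBP family list 3 of 6 rose, 4 over the list alone (median 0.44, adjusted p = 0.00856, adjusted p = 0.0872 with an estimated correlation). They were Cebpa, Cebpe and Cebpd (0.47 ± 0.093, adjusted p = 0.0203), while Cebpb did not pass (0.65 ± 0.25). Cebpa was lost without DL1 control replicates 1 and 3 (adjusted p = 0.0757 and 0.102), without irradiated replicates 2 and 3 (adjusted p = 0.0891 and 0.0510) and without the filter on the mean (adjusted p = 0.0599). Cebpe was lost without irradiated replicates 1 and 2 (adjusted p = 0.0628 and 0.0779), and Cebpd without DL1 control replicates 1 and 3 and irradiated replicate 2 (adjusted p = 0.0679, 0.0948 and 0.0728). The Notch target genes moved down, all 6 being lower and 0 passing, 2 over the list alone (median -0.25, adjusted p = 0.00994, adjusted p = 0.199 with an estimated correlation). Hes1 stood at 2.06 ± 0.449 against 2.95 ± 0.366 FPKM (-0.37 ± 0.12, adjusted p = 0.129), followed by Ccnd1 (-0.22 ± 0.075), Myc (-0.25 ± 0.10) and Nrarp (-0.30 ± 0.13). In the stem cell self-renewal list Meis1, a homeobox gene of stem cells, fell (-0.39 ± 0.085, adjusted p = 0.0310), as 1 of 18 genes over all genes and 3 over the list alone (median -0.085, adjusted p = 0.0134, adjusted p = 0.0872 with an estimated correlation). Next came Tal1 (-0.26 ± 0.072), Erg (-0.24 ± 0.066) and Kit (-0.18 ± 0.073). Meis1 was lost without 4 of the 6 libraries in turn, with adjusted p = 0.127 without DL1 control replicate 1.

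Smaller list shifts in irradiated cultures with DL1 came mostly without single genes that passed. Interferon response genes were higher, 0 of 18 passing over all genes in limma or over the list alone (median 0.18, adjusted p = 4.14e-04, adjusted p = 0.525 with an estimated correlation). The smallest p were those of Gbp3 (0.29 ± 0.079), Ifi27l2a (0.56 ± 0.18), Bst2 (-0.14 ± 0.051) and Oas2 (0.32 ± 0.12). Antigen presentation and dendritic cell genes were higher, 0 of 12 passing in either way (median 0.38, adjusted p = 0.00856, adjusted p = 0.721 with an estimated correlation). They were led by the class II genes H2-DMa (0.32 ± 0.12), H2-Ab1 (0.50 ± 0.23) and H2-DMb1 (0.43 ± 0.21) and their activator gene Ciita (0.52 ± 0.25). Cell cycle genes were lower by little, 0 of 28 passing in either way (median -0.084, adjusted p = 0.00994, adjusted p = 0.721 with an estimated correlation), among them Mcm2 (-0.14 ± 0.062), Pcna (-0.15 ± 0.072), Tk1 (-0.11 ± 0.057) and Mcm4 (-0.12 ± 0.066). Glycolysis genes were lower, the glucose transporter gene Slc2a3 falling (-0.47 ± 0.084, adjusted p = 0.0138) as 1 of 18, also over the list alone (median -0.081, adjusted p = 0.0134, adjusted p = 0.721 with an estimated correlation). Next came Pfkl (-0.13 ± 0.043), Pdk1 (-0.16 ± 0.055) and Hk1 (0.12 ± 0.042), without passing. Without irradiated replicate 1, Slc2a3 (adjusted p = 0.0594), the glycolysis list (adjusted p = 0.0932) and the antigen presentation and dendritic cell list (adjusted p = 0.0540) were lost, and without DL1 control replicate 2 the glycolysis list (adjusted p = 0.183). Notch1 (0.12 ± 0.091), Kit (-0.18 ± 0.073), Ly6a (-0.013 ± 0.094) and Cdkn1a (-0.15 ± 0.12) did not pass.

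Between irradiated and control cultures with DL1, 378 of 12025 genes passed, 301 higher and 77 lower, 13 of them, all higher, with an absolute log2 fold change of at least 1. Unadjusted p was under 0.05 for 2233, and 33.1% of genes had groups without overlap, where chance gives 10%. The count was 222 without the filter on the mean and 1744 with library weights. It was 252, 130 and 114 without DL1 control replicates 2, 3 and 1 and 130 and 105 without irradiated replicates 1 and 2.

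**Figure D3:**
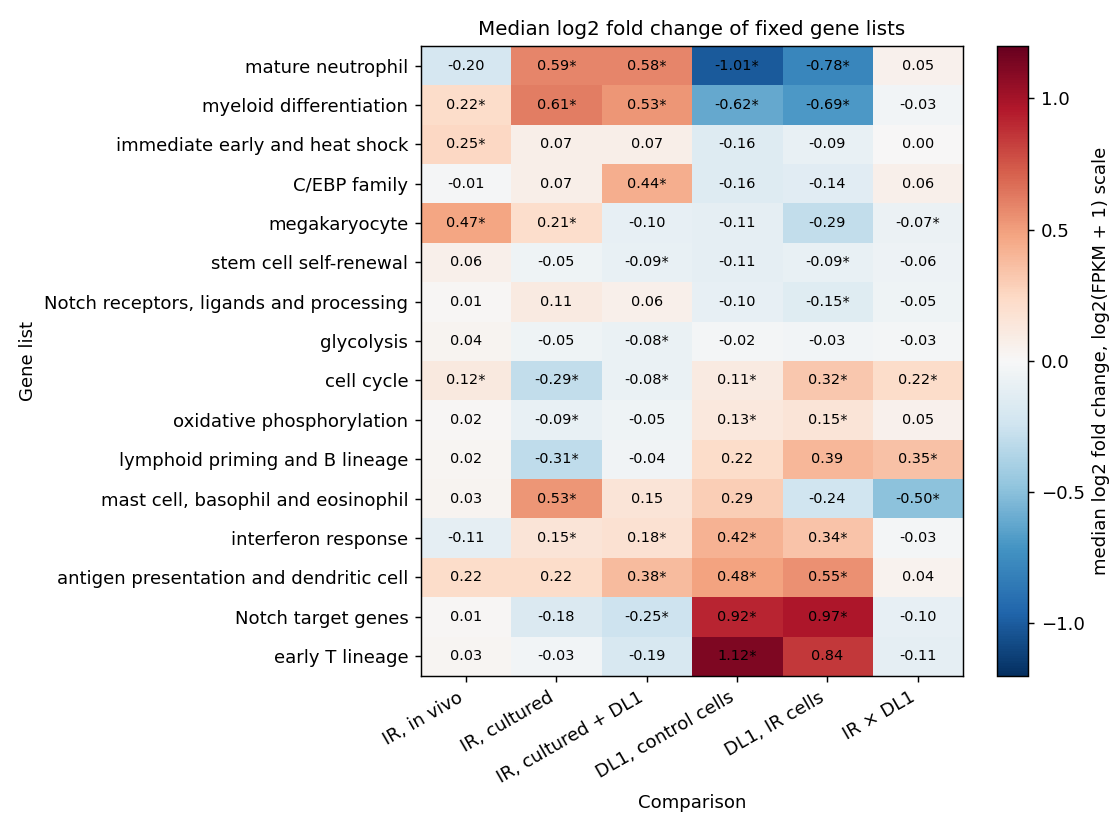
Median log2 fold change of the tested genes of each fixed list that passed in any of the 6 comparisons. Asterisks mark adjusted p under 0.05 under a preset correlation.

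Of single genes, the platelet chemokine gene Pf4 had the smallest p for a dependence of the irradiation change on DL1. It rose after irradiation without DL1, from 68.9 ± 10.6 to 177 ± 28.9 FPKM (1.35 ± 0.14, adjusted p = 1.57e-04). With DL1 it stood at 73.2 ± 4.13 and 50.6 ± 9.45, a difference between the changes of -1.89 ± 0.20, adjusted p = 0.00958. Its relative Ppbp went from 16.7 ± 3.90 to 51.2 ± 11.4 without DL1 and from 14.8 ± 2.15 to 9.37 ± 1.96 with it (-2.17 ± 0.28, adjusted p = 0.0143). Cd63, a tetraspanin gene of granules in mast cells and platelets, went from 94.6 ± 3.79 to 234 ± 17.4 and from 96.9 ± 10.2 to 135 ± 3.36 (-0.81 ± 0.10, adjusted p = 0.0143). Myl10 went from 7.77 ± 1.17 to 33.5 ± 3.39 and from 12.7 ± 2.39 to 18.6 ± 1.68 (-1.46 ± 0.18, adjusted p = 0.0143).

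Of the other genes with a difference between the changes, Gas6, a ligand of receptors that clear dying cells, went from 1.42 ± 0.537 to 6.52 ± 1.34 FPKM without DL1 and from 0.0510 ± 0.0220 to 0.144 ± 0.0808 with it (-1.53 ± 0.22, adjusted p = 0.0321). With DL1 it lay near 0, where adding 1 FPKM holds a change small, and its call was lost with a pseudocount of 0.1 (adjusted p = 0.282). The lysosomal sulfatase gene Sgsh went from 3.67 ± 0.0931 to 6.39 ± 0.503 and from 3.99 ± 0.234 to 4.25 ± 0.103 (-0.58 ± 0.091, adjusted p = 0.0428). The other direction was taken by Aqp9, from 16.5 ± 0.608 to 8.52 ± 0.498 and from 22.0 ± 0.230 to 16.2 ± 0.240 (0.46 ± 0.069, adjusted p = 0.0398). Hpgd, which degrades prostaglandins, went from 2.12 ± 0.417 to 0.808 ± 0.190 and from 1.55 ± 0.199 to 2.25 ± 0.297 (1.13 ± 0.16, adjusted p = 0.0321). The adaptor gene Ap1m2 went from 1.35 ± 0.225 to 0.777 ± 0.0647 and from 0.695 ± 0.0283 to 1.23 ± 0.128 (0.79 ± 0.12, adjusted p = 0.0428). Of 12025 genes 9 passed, 3 with a positive and 6 with a negative difference, 5 of them with an absolute difference of at least 1. Unadjusted p was under 0.05 for 1256. With the replicate number as a block 3 genes passed, all negative, Pf4 and Myl10 (adjusted p = 0.0263 for both) among them, and 19, these 9 among them, with a block in the irradiated cultures alone. Cebpa (-0.15 ± 0.12, adjusted p = 0.686), Notch1 (-0.12 ± 0.13), Hes1 (-0.27 ± 0.17), Cdkn1a (-0.30 ± 0.18), Kit (-0.21 ± 0.10) and Ly6a (-0.16 ± 0.13) did not pass.

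The difference between the changes passed for 4 of 19 lists. The cell cycle list was positive for all 28 genes (median 0.22, adjusted p = 3.19e-12, adjusted p = 0.374 with an estimated correlation). None passed over all genes in limma and 13 did over the list alone, with Mki67 (0.55 ± 0.10), Ccne1 (0.44 ± 0.10), Bub1b (0.39 ± 0.095) and Top2a (0.35 ± 0.087) having the smallest p. Mast cell, basophil and eosinophil genes were negative for all 14, Cd63 alone passing and 3 over the list alone (median -0.50, adjusted p = 4.36e-07, adjusted p = 0.229 with an estimated correlation). Next came Gzmb (-0.56 ± 0.11), Hdc (-0.56 ± 0.11) and Gata2 (-0.43 ± 0.16). In the megakaryocyte list Pf4 and Ppbp passed, 3 genes over the list alone (median -0.072, adjusted p = 0.00103, adjusted p = 0.209 with an estimated correlation). Because of these 2 genes its mean of -0.64 lay far from the median, and Itga2b came next (-0.73 ± 0.14). In lymphoid priming and B lineage 0 of 8 passed over all genes and 4 over the list alone (median 0.35, adjusted p = 0.00506, adjusted p = 0.229 with an estimated correlation), with Mef2c (0.36 ± 0.079), Flt3 (0.80 ± 0.19), Cd79b (0.53 ± 0.13) and Satb1 (0.36 ± 0.12). The p53 and DNA damage response list did not pass (adjusted p = 0.0711, adjusted p = 0.429 with an estimated correlation). Under a preset correlation it did, downward, with a replicate block in the irradiated cultures alone (adjusted p = 0.0399). The lymphoid list was lost without irradiated replicate 3 (adjusted p = 0.0519) and without the filter on the mean (adjusted p = 0.359). The gene calls depended on single libraries, with 189 genes passing without irradiated replicate 3 and 5 without irradiated replicate 1. They numbered 0 without control replicate 1, irradiated replicate 2 or irradiated replicate 2 with DL1, and between 1 and 4 without control replicate 2 or any other library with DL1. Pf4 was lost without control replicate 1 (adjusted p = 0.0575), irradiated replicate 2 (adjusted p = 0.0562) and irradiated replicate 2 with DL1 (adjusted p = 0.0526), and every other gene of the 9 without at least 4 libraries in turn (adjusted p up to 0.148).

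**Figure D4:**
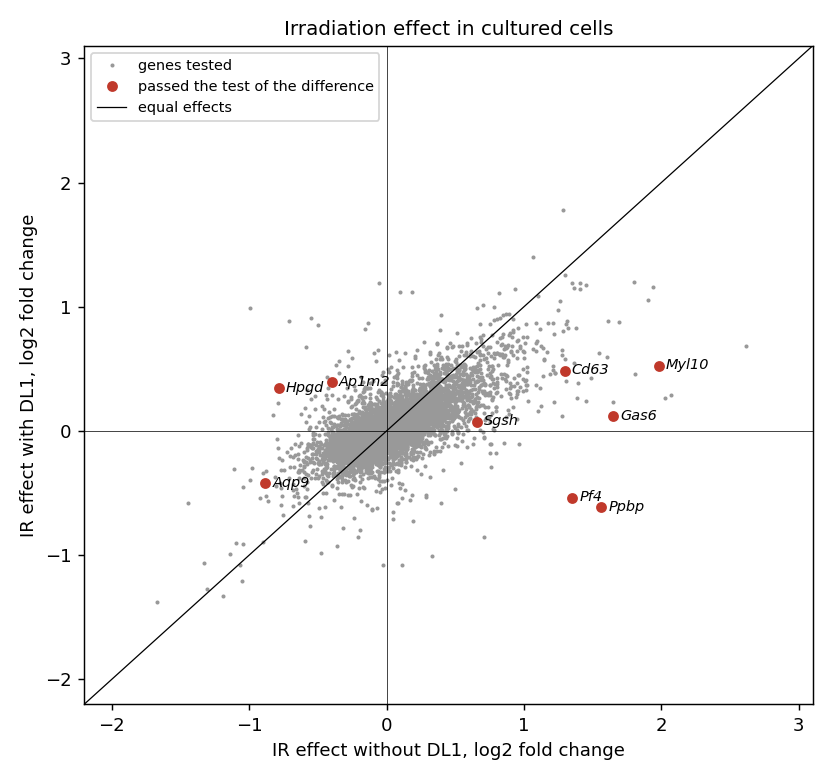
Log2 fold change after irradiation for each tested gene without DL1 (horizontal) and with DL1 (vertical). The 9 genes whose changes differed are in red, and the line marks equal changes.

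Across genes, the change after irradiation in culture was similar without and with DL1. Without against with DL1, the Pearson r was 0.701 and the Spearman rho 0.678 over 12025 genes, and none of 81 other pairs of splits of the same libraries gave an r as large, the highest being 0.521. Genes such as Elane, Ngp, S100a8 and Cebpa were among 271 that rose in both, where 41.6 would be shared if the calls were independent. Gimap6 was among 52 that fell in both, where 12.2 would be. Of the genes that fell without DL1, 1 rose with it, and 0 went the other way. Irradiated cultures of the same number deviated together without and with DL1 (r = 0.23, 0.14 and 0.35). The labels do not say whether they came from the same mice. If they did, both the r and the overlap of calls would be raised, which the splits do not remove. Freshly sorted against cultured cells gave r = 0.0689 and rho = 0.0660 over 11500 genes, with 47 of 81 other pairs of splits as large, and with 13 genes passing in freshly sorted cells this r does not tell how alike the changes were. It was -0.0356 without freshly sorted control replicate 1 and 0.159 without control replicate 2. Nkg7 rose in both (1.3 ± 0.11, adjusted p = 8.68e-05 in culture), whereas Selp (0.047 ± 0.18) and F2r (0.0011 ± 0.099) did not pass in culture.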

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

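The splits of the libraries were planned, and all other tests of explanations in this part were chosen only after the result was seen. The difference between the changes after irradiation with and without DL1 was tested for every gene and list, and 9 genes and 4 lists passed, 0 lists with an estimated correlation. For the genes, this difference in log2 fold change was -2.17 for Ppbp, -1.89 for Pf4, -1.53 for Gas6, -1.46 for Myl10, -0.81 for Cd63, -0.58 for Sgsh, 0.46 for Aqp9, 0.79 for Ap1m2 and 1.13 for Hpgd. For the lists, its median over genes was 0.22 in the cell cycle list, 0.35 in lymphoid priming and B lineage, -0.50 in mast cell, basophil and eosinophil genes and -0.072 in the megakaryocyte list. Aqp9 was higher in every freshly sorted irradiated library than in the controls (log2 fold change 0.23). It did not pass there, where the groups did not overlap for 12.7% of all genes. In irradiated cultures without DL1 it was lower in every library (-0.88). The gap of 1.11 was not tested, as the tables were normalized separately.

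For each comparison of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split gave 13 genes in freshly sorted cells (highest other split 3), 3568 for irradiation in culture (0), 378 with DL1 (1), 3154 for DL1 in control (0) and 4974 in irradiated cultures (0), so that 1 split, the real one, reached each count. For lists the real counts were 4, 8, 9, 8 and 9 and the highest other counts 9, 8, 7, 8 and 8, with 9, 4, 1, 3 and 1 splits reaching the real count. For the difference between changes, 100 of 200 splits were drawn, and 5 of them, the real one included, gave at least the 9 genes of the real split, with up to 1417, and 84 gave at least its 4 lists, with up to 11. The 4 other splits with as many genes all kept the true irradiation groups without DL1 and mixed those with DL1, so they hold the irradiation change itself. Chance is not excluded for these 9 genes and 4 lists.

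Macrophage genes were higher in irradiated than in control cultures without DL1 and lower with DL1. Of 24 tested markers, from a list of 27 written after the values of candidates had been seen, 21 rose after irradiation and fell with DL1 in control cells, and 7 rose after irradiation with DL1, although the cells had been sorted again as Lineage-negative LSK cells, a gate that should remove macrophages; 5 are also in the fixed lists, and 18 were tested in freshly sorted cells, of which 0 passed in limma. The most abundant, Lyz2, stood at 1982 FPKM in control, 3752 in irradiated, 412 in control with DL1 and 768 in irradiated cultures with DL1, and Apoe at 191, 618, 21.4 and 40.1. Scaling of the libraries is argued against, since all 21 kept both calls under each of 3 other scalings. Macrophages of one fixed makeup in varying share would give all markers one ratio of loss with DL1 to gain after irradiation. This ratio varied (median 0.597, range 0.264 to 1.56), and its leave-one-out range held the median for only 16.7% of markers. That cannot decide the question, since such a range is narrow with 3 libraries per group. The 5 markers in the myeloid differentiation list may also come from other myeloid cells, as other genes of that list moved the same way. What stays open is macrophages or their RNA, of fixed or changing makeup, and expression of these genes by LSK cells themselves, as an effect of irradiation and of DL1, which the design names and these tests did not separate.

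Fewer genes passed for irradiation with DL1 (378) than without (3568). The shallow library, irradiated replicate 2 with DL1, is argued against as the whole cause: without it 105 genes passed with DL1, against 130 and 285 without replicates 1 and 3 of its group and at least 2180 without DL1 with 1 irradiated library left out. With the spread taken from the 2 groups compared, rather than shared over the 4 groups, the counts were 997 and 1657, a ratio of 1.66 instead of 9.44 (from 118 to 1301 and from 245 to 3381 with 1 library left out). Much of the gap therefore cannot be told apart from how the spread is shared. With library weights the counts were 1744 and 3350. There the spread was still shared over the 4 groups, so the gap also depended on how libraries were weighted. The variance of log2 fold changes beyond their error was 0.377 of its value without DL1 (between 0.276 and 0.525 with 1 library left out), as smaller irradiation effects with DL1 would give. That effects are smaller with DL1 is a hypothesis, seen and tested on the same data.

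Jun rose in freshly sorted irradiated cells and Fos, its partner, was higher without passing, which could come from handling during the sort, since both genes respond to dissociation within minutes. Handling of irradiated replicate 2 alone is argued against for Jun, whose log2 fold change was 1.68 without that library (adjusted p = 0.00478), while Fos was 1.27 (adjusted p = 0.0504). Handling that differed between the groups cannot be told apart from an effect of irradiation: 1 of the 10 other immediate early members tested, Junb, was higher in every irradiated library than in every control, and their median log2 fold change was 0.25. The labels name no day or order of sorting that would separate these. A lasting effect of irradiation on Jun stays open as well, and in irradiated cultures, after 6 days of growth, Jun did not pass without (0.27, adjusted p = 0.219) or with DL1 (0.33, adjusted p = 0.282).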

How the results depend on the processing

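Leaving out each library, other pseudocounts, filters, scalings, variance models and the block were planned, and rescaling without ribosomal RNA-like rows and a block in 2 groups or in irradiated cultures alone were chosen after the results were seen. Of 6053 values of 377 results for named genes, 5556 kept direction and side of the threshold, 472 of those that passed no longer did, 13 passed that had not, and 12, all of genes that did not pass, changed direction. Of 336 calls of named genes 248 held under every alternative in which the gene was followed, 2 of 13 in freshly sorted cells, 61 of 89 for irradiation in culture, 13 of 35 with DL1, 78 of 93 and 94 of 97 for DL1 in control and irradiated cells, and 0 of 9 for the difference between changes. Single genes were not followed with only the 2 groups compared or at an absolute log2 fold change of at least 1. Nor were they followed without ribosomal RNA-like rows, and a gene below a raised filter was not counted as lost. On simulated data the smallest change was recovered least often in freshly sorted cells, for 8% of genes. Where not said, the cause was not tested.

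In freshly sorted cells (13 genes) 4 passed without the filter, 20 with robust variances, 20 with library weights, 7 with an absolute log2 fold change of at least 1, 23 without ribosomal RNA-like rows (12 higher, 11 lower, against 9 and 4), and 5 (without irradiated replicate 1) to 15 (without control replicate 2) with a library left out. Of 23 lists 4 passed, 0 with an estimated correlation, 0 with fry, and 2 (without irradiated replicate 2) to 6 (without control replicate 2) with a library left out. Cebpa was 0.088 with library weights, -0.28 without control replicate 3 and 0.25 without control replicate 2 (0.036 without irradiated replicate 2), and Ly6a -0.30 without control replicate 1, 0.048 without irradiated replicate 1 and 0.028 without control replicate 2.

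For irradiation in culture (3568 genes) 84 passed at an absolute log2 fold change of at least 1, 1657 with only the 2 groups compared, and 1876 (without control replicate 2) to 4700 (without irradiated replicate 3) with a library left out, and of 19 lists 8, or 0 with an estimated correlation. Kit was -0.041 without control replicate 3, -0.0066 and -0.0098 without irradiated replicates 2 and 3, and 0.090 without irradiated replicate 1. With DL1 (378 genes) 222 passed without the filter, 1744 with library weights, 13 at an absolute log2 fold change of at least 1, 997 with only the 2 groups compared, and 105 (without irradiated replicate 2) to 285 (without irradiated replicate 3), and of 19 lists 9, or 0 with an estimated correlation and 5 with fry. Ly6a was 0.013 with median-ratio scaling, -0.025 without irradiated replicate 2 and 6.8e-04 without irradiated replicate 1.

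For DL1 in control cells 359 of 3154 genes passed at an absolute log2 fold change of at least 1 and of 19 lists 8, or 0 with an estimated correlation, and Cdkn1a was -0.0078 without control replicate 2 and 0.22 without control replicate 3. In irradiated cells 441 of 4974 genes passed at that change, and of 19 lists 9, or 0 with an estimated correlation and 15 with fry, and Kit was -0.11 without irradiated replicate 1 and 0.0086 without irradiated replicate 2 with DL1. Fewer genes at a higher change follow from construction.

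For the difference between changes (9 genes) 18 passed with a pseudocount of 5, 3 without the filter, 5 at a mean FPKM of at least 5, 32 with library weights, 5 at an absolute difference of at least 1, and 0 (without control replicate 1) to 189 (without irradiated replicate 3), and of 19 lists 4, or 0 with an estimated correlation and 2 with fry. The correlation of irradiation changes without and with DL1 (0.701) was 0.766 at a mean FPKM of at least 5 and 0.625 (without irradiated replicate 1) to 0.720 (without irradiated replicate 3), and that of freshly sorted and cultured cells (0.0689) -0.0356 to 0.159, without freshly sorted control replicates 1 and 2.

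With the replicate number as a block, 9 genes passed in freshly sorted cells, 3415 for irradiation in culture, 352 with DL1, 3190 for DL1 in control and 3 for the difference between changes. In none of the first 4 did every library correlate best with its own number, so the numbers are not taken as pairs there. The difference between changes includes the irradiated cultures, where they did, and with a block there alone 19 genes and 5 lists passed, the p53 and DNA damage response list (adjusted p = 0.0399) being the added one. For DL1 in irradiated cells the block gave 4935 genes, or 4449 and 10 lists in the 2 groups alone. The former changed no call of a gene or list given here, the latter none of a list except the megakaryocyte list.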

Other observations

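The tests of opposed effects in the last paragraph were chosen only after the result was seen. In irradiated cultures without DL1 several genes outside the groups already described changed as well. In the antioxidant response list, 5 of 17 genes rose and 5 fell, so the list did not move as a whole (adjusted p = 0.947): the heme oxygenase gene Hmox1, which breaks down heme and is strong in macrophages, rose (0.59 ± 0.10, adjusted p = 0.00229), and the thioredoxin reductase gene Txnrd1 (-0.39 ± 0.068, adjusted p = 0.00214) and the cystine transporter gene Slc7a11 (-0.33 ± 0.071, adjusted p = 0.00638) fell. In the stem cell self-renewal list 4 of 18 genes fell and 0 rose (adjusted p = 0.433 with camera, 0.0104 downward with fry). Meis1, a homeobox gene of stem cells, fell from 8.61 ± 0.168 to 6.12 ± 0.972 FPKM (-0.44 ± 0.085, adjusted p = 0.00348). In the senescence and inflammatory secretion list 3 of 10 fell and 1 rose (adjusted p = 0.555), with the lamin gene Lmnb1, which falls in senescent cells, lower (-0.39 ± 0.061, adjusted p = 0.00108).

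DL1 in irradiated and in control cultures changed the same genes in much the same way, with a Pearson r of 0.903 and a Spearman rho of 0.784 across 12025 genes. Both comparisons called 1275 genes higher, where 408 would be shared if independent, and 1288 lower, where 251 would be, and 3 went each opposite way. Tcf7, Hes1, Itgax and Cd7 were among those higher in both and Fn1, Apoe and Lyz2 among those lower in both.

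Genes that rose after irradiation tended to fall with DL1. In control cultures 741 genes, Apoe, C1qb and Lyz2 among them, were both higher after irradiation and lower with DL1, where 204 would be if the calls were independent. The 2 comparisons share the control libraries, which pushes their changes to the same sign: the correlation was -0.391, against a median of 0.491 in 20 simulated sets without effects. The main effects of irradiation and of DL1 over all 4 groups share no control in this way. Their r was -0.557 (-0.597 to -0.510 without 1 library) and rho -0.519. The covariance was -0.0449, against -5.82e-04 from error alone, which ignores genes that vary together. No splits were tested here, and those for the irradiation changes reached an absolute r of 0.521. That DL1 opposed the irradiation changes is a hypothesis, seen and tested on the same data.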
